A study of Solanum lycopersicum with 6 samples.

How the data were processed

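RNA was taken from the equatorial pericarp of greenhouse-grown tomato fruit at 38 days after anthesis, from WT and from transgenic jmj7 lines in the Ailsa Craig background, with 3 libraries per group. Per the submitters' processing notes, HISAT2 was used; its version, the genome build, the gene counter and the strand setting are not given in the sources used here. The authors' deposited table lists genes by Solyc identifier, in which the digits after the prefix name the chromosome, and holds per-library read counts, per the file headers. It also holds the authors' FPKM values (fragments normalized for gene length and total reads) for each library, per the file headers. A further deposited value per library is a signal that equals the read count divided by 1 size factor per library, called the normalized count here. The authors' log2 fold changes, and p-values with adjusted p-values, are given for the comparison of both groups, per the file headers. The table was selected before deposit: each of its 8703 genes has an absolute log2 fold change above 1 and a p-value of at most 0.0499.

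Library columns were assigned by name for WT. The prefix of the remaining columns is in no label, and these were assigned to jmj7 by elimination, with the same replicate numbers. The deposited size factors, recovered from the ratio of count to normalized count, were 1.16, 1.07 and 1.31 for WT and 1.07, 0.759 and 0.79 for jmj7. Reads in the table's genes per library ranged from 7508105 to 15254146, and the 10 most abundant genes took 12.2% to 12.5% of them in WT and 25.9% to 26.4% in jmj7. The median coefficient of variation between replicates, for genes of at least 1000 normalized counts, was 3.28% in WT and 2.45% in jmj7. Each pair of replicates differed by more than sampling noise, with a chi-square per gene from 1.63 to 3.68. None was therefore counted as the same library sequenced again. This does not show that the replicates came from separate plants or fruits.

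Read counts were tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, prior count 0.125), after filterByExpr with a minimum count of 10, with Benjamini-Hochberg adjusted p under 0.05. The design fixed before the data were examined named TMM scaling. The deposited size factors were used in its place, because TMM assumes that most genes are unchanged and the table holds only called genes. This choice was made after the table had been seen and after an exploratory run had shown the counts of called genes under TMM, the deposited factors and total-read scaling. The overall counts of called genes with TMM are therefore printed beside the main ones; list tallies and folds are given with the deposited factors. With TMM, the 97 tested list members gave 53 higher and 44 lower calls, the numbers found with the deposited factors. The standard error of a log2 fold change is the Wald error from the fitted means and quasi-likelihood dispersions, and never less than the counting (Poisson) error; genes with a group at 0 reads have none. Means are given with the SD over 3 libraries. Folds against a group at 0 reads, and ratios for a group of 1 to 3 reads, use reads pooled over a group and divided by its summed size factors. The former use a floor of 3 reads over the group, and the latter have an exact 95% binomial counting interval. Both hold for the deposited size factors and move with the scaling. The fit was tested on simulated counts for 7622 genes with 200 genes changed. It recovered 8.96% of the genes changed 1.1-fold, 77.6% of those changed 1.5-fold and 87.9% of those changed 2-fold, and 5 of 121 calls were false. Of its log2 fold changes, 95.1% lay within a nominal 95% Wald interval of the simulated value. The simulated counts had a common dispersion and the same size factors as the fit, and most genes were unchanged. The simulation therefore does not cover errors from the scaling or from the selection of the table's genes.

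Gene lists were written before the data were examined, from general knowledge of tomato ripening, with 170 identifiers. Neither the deposited table nor the reference gene table (assembly SLM_r2.1, which holds no Solyc identifiers) pairs these identifiers with symbols. Apart from JMJ7, whose identifier could not be checked, a symbol was printed only where the reference has it, directly or as a synonym, on the chromosome that the identifier names and in a compatible order, with a tolerance of 0.5 Mb. This left 134 symbols checked, 22 absent from the reference, 5 in neighbouring copies not told apart, and 9 contradicted. Those 9 were taken out of the lists, and the unmatched identifiers stayed in the counts without being named. This policy, the aliases used and the copies left unnamed were set after the table and the reference had been seen. Of the 161 identifiers kept, 102 have a row in the table used here. Lists based on gene descriptions could not be used, since neither source holds descriptions. Set tests such as camera and fry need genes that were not called, and were not run.

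The genes named were fixed by a rule before the data were examined: JMJ7, RIN, NOR, CNR, NR, DML2, ACS2, ACS4, ACO1, E4, E8, PSY1, PG2a and PL. Added to these were the 4 called members of each list with the largest change and a mean of at least 1 FPKM, and the 10 highest and 10 lowest called genes with groups that do not overlap and at least 5 FPKM in the higher group. Of the last, only some identifiers are printed, because most have no names. HB-1, GLK1, CAB4 and CAB7 are named outside the rule, chosen after their values were seen. Some other list members that the rule did not pick are described without a symbol. The alternatives tried were size factors recomputed over the table, the Wald test of DESeq2 1.42.0, no filter, a filter of 5 FPKM in 3 libraries, the replicate number as a block, each library left out, and other thresholds on the authors' calls. TMM, displaced as the main scaling after the data had been seen, was kept as an alternative, and total-read scaling was added at that time. The relative totals for total-read scaling were recovered from the ratio of count to FPKM, as a median over genes. They are not the sums of reads in the table's genes. Tables and plots were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.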

Results

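Transcripts of tomato (Solanum lycopersicum) fruit pericarp, the fleshy fruit wall, were counted by RNA sequencing at 38 days after anthesis in the Ailsa Craig background. Wild-type fruit (WT) gave 3 libraries and the transgenic lines called jmj7 gave 3. The title of the series names the target as a histone demethylase, an enzyme that removes methyl groups from histones. It places this gene beside DNA demethylation, ethylene signalling and the transcription factors of fruit ripening, which sets the question of the comparison. The columns of the second group carry a prefix that is in no sample label; they were taken as jmj7 by elimination, since WT was the other of the 2 groups and each has 3 numbered columns. Every direction given for jmj7 rests on this assignment. The table used here holds 8703 genes, all already called different by the authors, so genes outside it were not analysed here. Its genes took up 8050301, 7508105 and 9155968 reads in the WT libraries and 15254146, 10937853 and 11365480 in the jmj7 libraries. These sums cover part of each library, and the full depths are not given in the sources used here.

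The identifier listed for JMJ7, the targeted gene, has no row in the table used here; the reference gene table has no symbol to check that identifier, so the target's level could not check the labels. Many genes linked to fruit ripening differed between jmj7 and WT. Both groups were sampled at the same age, 38 days after anthesis. A difference in ripening stage between the groups therefore cannot be told apart from other effects of the genotype on single genes. RIN, the MADS-box regulator of ripening, rose from 15.8 ± 4.16 normalized counts in WT to 25689 ± 687 in jmj7 (SD, n = 3 per group), and PG2a, the polygalacturonase that degrades pectin in ripe fruit, rose from 3.01 ± 1.41 normalized counts in WT to 661085 ± 23253 in jmj7. PG-beta, a pectin-associated subunit of polygalacturonase, fell from 52485 ± 1809 normalized counts in WT to 177 ± 23.5 in jmj7, and GLK2, a regulator of chloroplast development in green fruit, fell from 1187 ± 147 normalized counts in WT to 12.6 ± 2.23 in jmj7. Of 7622 genes tested with edgeR's quasi-likelihood test, 2837 were higher and 4785 lower in jmj7 at an adjusted p under 0.05. With a fold change of at least 2 as well, 2828 were higher and 4777 lower.

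The size of the changes differed by direction. Beyond 4-fold, 1051 genes were higher and 2972 lower, and beyond 32-fold 244 were higher and 871 lower. The authors' deposited table itself marks 3087 genes as higher and 5616 as lower, and its smallest absolute log2 fold change is 1.00. Because that table was chosen on the difference tested here, passing the test again is no independent evidence, and adjusted p-values over its genes do not control false calls over the whole genome. The split moved with the scaling of the libraries: with TMM factors, the scaling fixed before the data were examined, 2843 genes were called higher and 4699 lower, of which 2843 and 3962 changed at least 2-fold. With size factors recomputed over these genes alone, 47.3% of the called genes and 53.6% of the genes changed at least 2-fold were higher, against 37.2% of each with the deposited size factors. With total-read scaling, 36.0% of the called genes and 23.6% of the genes changed at least 2-fold were higher.

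The gene lists include members with no row in the table used here. These were not analysed here, and each tally covers only members that the authors had already called. Every one of the 7622 genes tested was called, 2837 higher and 4785 lower. A call of a tested list member was therefore set in advance, and each split is to be read against these counts. Of 16 transcription factors linked to ripening, 12 were tested and 4 have no row in the table used here. Of those tested, 8 rose and 4 fell in jmj7, and 12 were called when adjusted over the list alone. RIN (Solyc05g012020.3) had a log2 fold change of 10.63 ± 0.191 (SE; edgeR adjusted p = 2.56e-47). NOR (Solyc10g006880.3), a NAC factor required for ripening, rose from 233 ± 7.27 normalized counts in WT to 15073 ± 426 in jmj7, a log2 fold change of 6.01 ± 0.0567 (SE; edgeR adjusted p = 7.76e-45). FUL1 (Solyc06g069430.3), another MADS-box factor, rose 25.7-fold, and CNR (Solyc02g077920.3), an SBP-box factor, rose 4.35-fold, from 3582 ± 134 normalized counts in WT to 15585 ± 188 in jmj7. GLK2 (Solyc10g008160.3) was 93.3-fold lower, with a log2 fold change of -6.54 ± 0.287 (SE). With size factors recomputed over the table's genes, HB-1, one of the 4 that fell, turned to higher and 1 other, GLK1, lost its call.

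The ethylene genes moved in both directions. Of 13 genes of ethylene synthesis, 5 have no row in the table used here, 3 were below the low-count filter and 5 were tested. Of those tested, 3 rose and 2 fell, and 5 were called when adjusted over the list alone. ACS2 (Solyc01g095080.3) and ACS4 (Solyc05g050010.3), which encode ACC synthases of the ripening fruit, rose 49-fold and 54.2-fold. For ACS2 this was a change from 412 ± 42.2 normalized counts in WT to 20196 ± 192 in jmj7 (SD, n = 3; log2 fold change 5.62 ± 0.0519 SE, edgeR adjusted p = 7.19e-44). ACO6 (Solyc02g036350.3) rose 5.72-fold and ACO5 (Solyc07g026650.3), also an ACC oxidase gene, was 31.5-fold lower. Of 19 genes of ethylene perception and response, 14 have no row and 5 were tested; of these 3 rose and 2 fell, and 5 were called when adjusted over the list alone. NR (Solyc09g075440.3), an ethylene receptor gene, rose from 2305 ± 37.8 normalized counts in WT to 30886 ± 778 in jmj7, and ETR6 (Solyc09g089610.3), also a receptor gene, fell from 3069 ± 47.1 normalized counts in WT to 467 ± 40.3 in jmj7. E8 (Solyc09g089580.3), an ethylene-responsive fruit gene, rose 921-fold, and ERF.E4 (Solyc01g065980.3), an ethylene response factor, rose 3.95-fold. The name E8 rests on a synonym in the reference gene table, where another gene on a different chromosome also bears it. ACO1 and E4 have no row in the table used here. With size factors recomputed over these genes, each of these lists kept 1 lower gene.

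Of 12 genes of DNA methylation and demethylation, 5 have no row in the table used here and 7 were tested. Of those tested, 1 rose and 6 fell, and 7 were called when adjusted over the list alone. Over all genes tested, 4785 of 7622 were lower, and whether the split is particular to this list was not tested. DML2 (Solyc10g083630.2), a DNA demethylase of ripening fruit, was the one that rose, from 4657 ± 119 normalized counts in WT to 24039 ± 386 in jmj7 (SD, n = 3). Its log2 fold change was 2.37 ± 0.0346 (SE; edgeR adjusted p = 1.06e-36). DML1 (Solyc09g009080.3), a related demethylase gene, was 8.03-fold lower. The maintenance methyltransferase gene MET1 (Solyc11g030600.3) fell from 1443 ± 70.9 normalized counts in WT to 438 ± 31.7 in jmj7. CMT4 (Solyc08g005400.3), a chromomethylase gene, was 7.73-fold lower. With size factors recomputed over the table's genes, MET1 was 1.40-fold, DML1 3.43-fold and CMT4 3.31-fold lower. The filter of 5 FPKM in 3 libraries left 3 lower genes in this list.

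**Figure D1:**
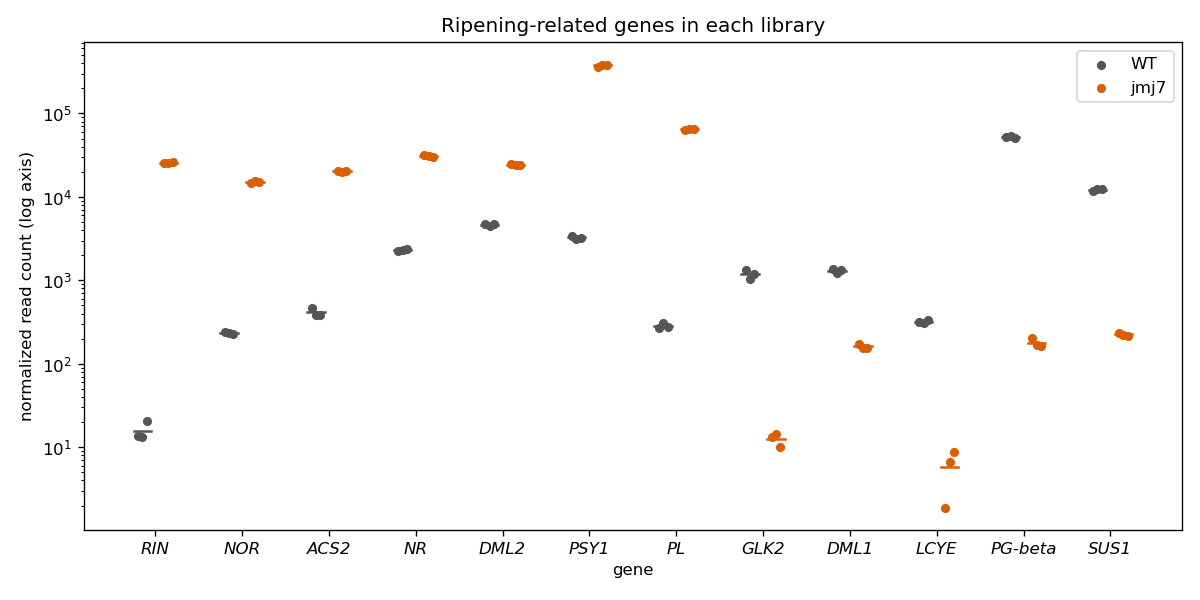
Normalized read counts of 12 genes in the 3 WT (grey) and 3 jmj7 (orange) libraries on a log axis; each point is 1 library and each bar the mean of its group. RIN, NOR, ACS2, NR, DML2, PSY1 and PL lie higher in the jmj7 libraries, and GLK2, DML1, LCYE, PG-beta and SUS1 lie lower.

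Of 24 carotenoid genes, 10 have no row in the table used here and 14 were tested. Of those tested, 12 rose and 2 fell in jmj7, and 14 were called when adjusted over the list alone. PSY1 (Solyc03g031860.3), the phytoene synthase of ripening fruit, rose from 3264 ± 138 normalized counts in WT to 377525 ± 12541 in jmj7 (SD, n = 3), a log2 fold change of 6.85 ± 0.0366 (SE; edgeR adjusted p = 6.67e-48). ZISO (Solyc12g098710.2), a carotene isomerase gene, and GGPPS2 (Solyc04g079960.1), which makes the geranylgeranyl precursor, rose 106-fold and 65.8-fold. LCYE (Solyc12g008980.2), which encodes the cyclase that leads towards lutein, fell from 321 ± 15.8 normalized counts in WT to 5.77 ± 3.56 in jmj7. Both listed genes of chlorophyll breakdown rose, and both were called when adjusted over the list alone; SGR1 (Solyc08g080090.3), a stay-green gene, rose from 348 ± 39.1 normalized counts in WT to 34500.3 ± 699.6 in jmj7.

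Of 17 cell wall genes, 4 have no row in the table used here and 13 were tested. Of those tested, 9 rose and 4 fell in jmj7, and 13 were called when adjusted over the list alone; with size factors recomputed over the table's genes, 3 of the lower genes kept their call. PG2a (Solyc10g080210.2) had 11 reads in all WT libraries together and a log2 fold change of 17.64 ± 0.435 (SE; edgeR adjusted p = 7.72e-52). MAN4a (Solyc01g008710.4), an endo-mannanase gene, had 2 reads over the WT libraries and 200254 over the jmj7 libraries, a ratio of 135457 between pooled reads divided by summed size factors, with an exact 95% counting interval from 37498 to 1118518. The pectate lyase gene PL (Solyc03g111690.3) rose from 284 ± 23.6 normalized counts in WT to 64326 ± 1164 in jmj7. PMEU1 (Solyc03g123630.3), a pectin methylesterase gene, and PG-beta (Solyc05g005560.4) were 375-fold and 291-fold lower. Intervals of this kind cover counting error only.

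Of 15 aroma genes, 3 have no row in the table used here, 1 was below the low-count filter and 11 were tested. Of those tested, 6 rose and 5 fell, and 11 were called when adjusted over the list alone. AAT1 (Solyc08g005770.3), an alcohol acyltransferase gene, and the lipoxygenase gene LOXC (Solyc01g006540.3) rose 1159.8-fold and 962-fold. LOXF (Solyc01g006560.3), which lies near LOXC on the same chromosome and is similar to it, was 51.3-fold lower on 4 reads in jmj7, a log2 fold change of -5.68 ± 0.796 (SE); how reads shared by such copies were assigned is not given in the sources used here, so both values are uncertain. SAMT1 (Solyc09g091550.3), a salicylate methyltransferase gene, had 1364 reads in WT and 0 in jmj7. With the deposited size factors and a floor of 3 reads over the group, it was at least 336-fold lower. Of 12 genes of sugar, starch and acid metabolism, 4 have no row and 8 were tested; of these 3 rose and 5 fell, and 8 were called when adjusted over the list alone. With size factors recomputed over the table's genes, 4 of the lower genes kept their call. The vacuolar invertase gene VI (Solyc03g083910.4) rose from 5739.6 ± 205 normalized counts in WT to 469509 ± 919 in jmj7, while SUS1 (Solyc12g009300.3), a sucrose synthase gene, and AGPL1 (Solyc01g109790.3), a subunit of the starch pathway enzyme ADP-glucose pyrophosphorylase, were 53.9-fold and 75.6-fold lower. GBSS (Solyc08g083320.3), the starch synthase of amylose, was 5.57-fold lower.

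Of 10 genes of the glycoalkaloid pathway, which makes the bitter steroidal alkaloids of green tomato, 1 has no row in the table used here, 1 was below the low-count filter and 8 were tested. All 8 fell in jmj7, and 8 were called when adjusted over the list alone. GAME12 (Solyc12g006470.2) fell from 1175 ± 39.1 normalized counts in WT to 5.47 ± 3.6 in jmj7 (SD, n = 3). GAME4 (Solyc12g006460.2), GAME18 (Solyc07g043500.1) and GAME11 (Solyc07g043420.3) were 130.0-fold, 93.9-fold and 89-fold lower, with log2 fold changes of -7.02 ± 0.617, -6.55 ± 0.472 and -6.48 ± 0.194 (SE). Of 9 flavonoid genes, 1 has no row and 8 were tested; of these 6 rose and 2 fell, and 8 were called when adjusted over the list alone. The chalcone synthase genes CHS1 (Solyc09g091510.3) and CHS2 (Solyc05g053550.3) rose 87.9-fold and 3.35-fold, and MYB12 (Solyc01g079620.3), a regulator of flavonol genes, rose 3.55-fold. The 2 that fell, which the naming rule did not pick, were 40.5-fold and 42.9-fold lower.

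**Figure D2:**
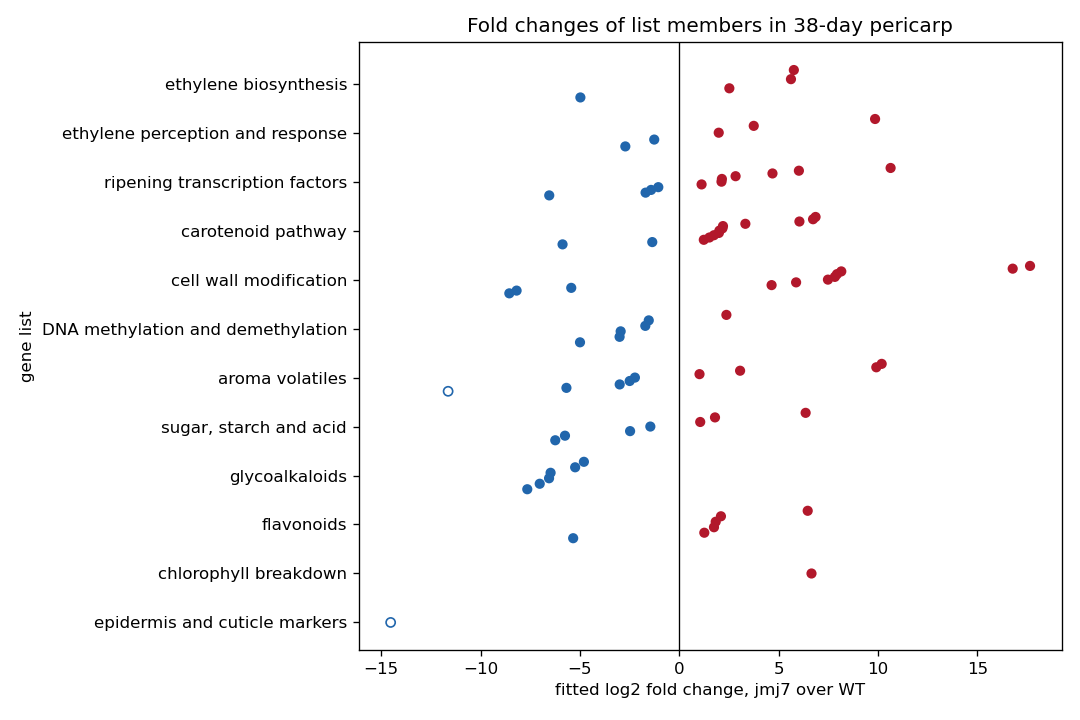
Fitted log2 fold changes (jmj7 over WT) of 80 list members with a checked symbol, in 12 lists; red points are higher and blue points lower in jmj7, and each point is 1 gene. The 2 open circles are genes at 0 reads in jmj7, whose fitted value depends on the prior count; the glycoalkaloid points all lie below 0, while the carotenoid points lie on both sides of it.

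Markers of the epidermis and cuticle, the outer layer of the fruit wall, were 8 in number; 4 have no row in the table used here and 4 were tested. All 4 fell, and 4 were called when adjusted over the list alone. CD1 (Solyc11g006250.2), a cutin synthase gene, had 10139 reads over the WT libraries and 0 over the jmj7 libraries. It was at least 2498-fold lower with the deposited size factors and a floor of 3 reads over the group. Solyc08g081220.1, also in this list, had 4701 reads over the WT libraries and 0 over the jmj7 libraries, at least 1158-fold lower by the same floor. Solyc10g075110.2 was 37.9-fold lower, and 17.2-fold lower with size factors recomputed over the table's genes. The smallest change of the 4 was in a lipid transfer protein gene whose neighbouring copies were not told apart. It fell 3.19-fold, from 7058 ± 444 normalized counts in WT to 2209 ± 72.3 in jmj7. With recomputed size factors it was 1.36-fold lower. The 3 listed genes of abscisic acid metabolism have no row in the table used here. Over all genes, 10 of highest and 10 of lowest fold change were selected, and most of their identifiers are not paired with names. Among the highest, Solyc12g088220.2 had 0 reads in WT and 28938 ± 1256 normalized counts in jmj7, at least 33948-fold higher with the deposited size factors. This identifier is also counted among the higher members of the aroma list. Solyc08g066240.3 rose from 3.02 ± 1.82 normalized counts in WT to 222599 ± 3792 in jmj7. Solyc08g066245.1, Solyc08g066250.3 and Solyc08g066260.3, with nearby locus numbers, were also among the 10 highest. Whether these are similar copies, and how shared reads were assigned, is not given in the sources used here. Among the lowest, Solyc10g005320.3 had 0 reads in jmj7 and 3338 ± 191 normalized counts in WT, at least 2910.4-fold lower with the deposited size factors. Of the 7622 genes tested, 7602 had groups that did not overlap; chance gives 10% for 3 against 3, and these genes had been selected for a difference. The labels do not say that the replicates were separate plants or fruits. The p-values set the group difference against the spread between these libraries only, and may not extend to other plants or lines.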

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

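The deposited size factors took the place of TMM, the scaling named in the design fixed beforehand, only after the data had been seen; TMM thus became an alternative, total-read scaling was added at that time, and the other alternatives were planned. All 61 genes picked by the naming rule that were tested kept their direction and their call in each of 791 values under these alternatives. Most of them were picked for a large change, so this says little about other genes. With size factors recomputed over the table, 528 genes changed direction, and 6391 of the 7554 tested were called. Of the 97 tested list members, 1 changed direction and 5 lost their call under that scaling. Of 396 counts under alternatives, 378 stayed within 1.5 times the count reported. Counts of 0 in both were included, and the genes counted had all been called by the authors, so this says little about robustness. Scalings shifted the median log2 fold change by 1.23 with size factors recomputed over the table, by 0.32 with TMM and by -0.56 with total-read scaling. The filter of 5 FPKM in 3 libraries tests fewer genes by construction: it called 4800 genes, 2607 of them lower, and 4794 at least 2-fold, 2603 of them lower. Under it the lower members numbered 1 in ethylene biosynthesis, 1 in ethylene perception and response, 3 in DNA methylation and demethylation, 3 in aroma volatiles and 1 in flavonoids. Total-read scaling left 1493 genes higher by at least 2-fold, through its shift. Size factors recomputed over the table left 2544 lower by at least 2-fold, with lower members of 1 in ethylene biosynthesis, 1 in ethylene perception and response and 2 in ripening transcription factors; they set the median gene of a table of called genes near 0 by construction. The DESeq2 Wald test and no low-count filter, which test more genes, each gave 4 lower members in ethylene biosynthesis. A threshold of 2 on the authors' absolute log2 fold change kept 5046 of their calls, 1284 of them higher. With each library left out in turn, between 7730 and 7877 genes were called. The replicate block called 7622 genes, as without it, and could not have called more, since every tested gene was called without it. Correlations of same-numbered libraries were -0.028, 0.025 and -0.01, so no shared deviation was seen. This cannot exclude a pairing of the samples, because the labels do not say what the numbers mean. The pseudocount and quantile alternatives were planned only for a table without counts and were not run, edgeR's prior count was not varied, and camera and fry were not run. Depth limits genes of few reads: 1081 genes of the table fell below the low-count filter.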

Other observations

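The photosynthesis list was chosen after the values of its members had been seen, and the tests in the paragraphs that follow it were written before their results were seen, although the counts of called genes under the scalings were known by then; the thinning to other scalings was chosen after the first thinning had been seen. Of 20 listed identifiers, 2 have no row in the table used here. Of 18 tested genes for chlorophyll a/b-binding proteins and the small subunit of Rubisco, the carbon-fixing enzyme, 18 fell in jmj7 and 0 rose. Their median log2 fold change was -7.23, also with genes at 0 reads set to the floor of 3 reads over the group. CAB7 (Solyc10g006230.3) fell from 30293 ± 675 normalized counts in WT to 3106 ± 129.7 in jmj7 (SD, n = 3), and CAB4 (Solyc07g047850.3) fell from 27547 ± 813 normalized counts in WT to 697 ± 27.1 in jmj7. They were 9.74-fold and 39.5-fold lower, less than the list median of 150-fold. Cab-1D (Solyc02g070990.1), which the naming rule picked, had 16287 reads over the WT libraries and 0 over the jmj7 libraries. With the deposited size factors and the same floor, it was at least 4013-fold lower. Many genes of this list have near-identical copies. How shared reads were assigned is not given in the sources used here, so single values are uncertain.

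More genes were lower than higher in jmj7, 2972 against 1051 beyond 4-fold. Gene length as the source is argued against: with the genes split into 3 groups by relative length, the share of lower genes was 62.0% at the smallest, with a binomial standard error of 0.992%. Library scaling stays open. A common log2 shift of 0.75 (bootstrap SD 0.0202) balances these counts, but some shift would balance any such counts. The shift of 0.75 is larger than the TMM shift of 0.32, so by the bound written beforehand scaling would be argued against. That bound was judged too low afterwards, because size factors recomputed over the table shifted folds by 1.23. Those factors set the median of called genes near 0 by construction, so the comparison of shifts decides nothing. No genes known to be unchanged are in the table, so scaling and genotype cannot be told apart here.

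More genes were at 0 reads in jmj7 than in WT: 701 of 5616 lower genes (12.5%) had 0 reads in all jmj7 libraries, and 171 of 3087 higher genes (5.54%) had 0 in all WT libraries. Thinning the WT reads to the jmj7 size factors gave a share of higher genes at 0 of 6.02% (SD 0.107% over 20 draws). Thinning to TMM factors gave 6.44% (SD 0.159%) and thinning to recomputed size factors gave 7.81% (SD 0.185%), both still below 12.5%. These shares show what a loss of depth does to the higher genes only. The lower genes had larger folds, 871 against 244 beyond 32-fold, so the thinning cannot decide whether lower effective depth in jmj7 is the source. Genotype, ripening stage and tissue makeup stay open as well and were not tested.

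Neighbouring genes changed in the same direction in 67.6% of 2810 adjacent pairs (locus numbers at most 10 apart). Shuffling directions within chromosomes 1000 times gave 54.3% on average and 56.8% at most, which argues against chance placement. Tandem copies of similar length are argued against as the whole source, since among 1722 pairs whose lengths differed over 1.5-fold the share was 67.6%, against at most 58.4% after shuffling. Copies of unlike length and shared control of neighbouring genes stay open and may both contribute; no biological explanation was tested.

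Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many called genes (7622), and the highest of the others gave 0. For genes changed at least 2-fold, 1 split of 10 did (7605), and the highest of the others gave 0. With 10 splits no share can fall under 0.05. The test was edgeR's, and at an unadjusted p under 0.05 the other splits gave 0 genes as well. No other tool was run on them. The genes had been selected for the real split, so any other split moves their difference into the spread within its groups. The lack of calls in the other splits was therefore set in advance and adds no evidence.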
